A study of Mus musculus with 6 samples.

How the data were processed

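Expression was measured in cultured muscle satellite cells, the stem cells of skeletal muscle, from the hind limbs of 3 adult male Swiss Webster mice. Per the labels' protocols, minced muscle was plated repeatedly, with preplating on plastic to remove fibroblasts, until purified myoblasts remained. Proliferating cultures were kept with bFGF at 6.6 ng/ml and differentiated cultures spent 72 hours in medium with 10% horse serum and insulin (1 mM as labelled). Biotin-labelled cRNA was made from 5 µg of total RNA and hybridised to 1-colour CodeLink arrays, per the labels. There were 3 arrays per group, 6 in all.

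The deposited values are intensities on a linear scale with medians a little under 1 on every array. They include a few values at or under 0, so a background had been subtracted. Bacterial control mRNAs were added for intensity normalization, per the labels' protocols. The scanner software, the background method, the scaling step and the reason for missing values are not given in the sources used here. No detection call was used. The number of arrays limits the precision.

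The table held 10500 features, of which 10128 had a value on all 6 arrays, 311 had none and 61 lacked a value on 1 to 3 arrays. The platform annotation gave 1 gene symbol for 6373 features, several for 0 and none for 4127. All 6373 were matched by Entrez ID to the GRCm38.p6 gene table, and 0 symbols changed. Features without a symbol were tested and counted but not named.

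Values under the 1st percentile of positive values, an intensity of 0.0236, were set to it before taking log2. The log2 medians of the arrays lay within 0.089 of each other, under the tolerance of 0.2 fixed for this purpose, so no further scaling was applied. Features with at least 2 values per group, 10186 in all, were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are differentiated minus proliferating, given as log2 values with the SE of the fit, with 3 arrays per group.

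For gene lists, 1 probe per gene was used, the one with the highest mean. The 37 lists held 848 entries, 533 of them named on the array, and each had at least 4 measured genes. They were tested with camera from limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 37 lists. Camera compares a list with all other genes, while fry asks whether its genes move one way on balance.

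The samples, groups, main tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls past the threshold with no overlap of the groups. It added a fixed panel of 22 genes, of which 14 were named on the array, and 5 housekeeping genes. From each list it took up to 2 rises and 2 falls past the threshold, or the gene with the smallest p where none passed. It gave 72 genes. Pax7, Ccnb1, Mki67, Id1, Myh3, Myh8, Acta1 and Des from the panel were not analysed here.

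Both cultures of each mouse share a number in the labels, and the series design states that each mouse gave both, so the numbers pair the arrays. After removing group means, arrays of the same number correlated across probes at 0.42, 0.37 and 0.28, each over the 0.1 required. The main test had no block for mouse because no analysis method was stated, and fits with mouse as a fixed or random block were alternatives.

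Alternatives covered the floor, a pseudocount, quantile normalization, median centring, dim probes, missing values, the variance prior, the threshold, the pairing, the probe per gene, the set test, and leaving out each array or mouse. The procedure was tested on simulated data for the comparison of differentiated with proliferating cells, in 10 simulations of 10186 probes with 200 changed. A list of 26 ribosomal protein genes was shifted as well. Without a block it found 77.2% of 16-fold and 4.3% of 4-fold changes with 0.2 false calls per simulation, and with mouse as a random effect 95% and 48.3% with 6.3 false calls. Every simulated probe had a mouse share of variance of 0.5 and was drawn independently of the others. Real probes can differ in both respects, so these rates need not hold for them.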

Results

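Gene expression was measured on 6 arrays, with 3 of proliferating and 3 of differentiated satellite cell cultures, 1 of each from every one of 3 mice. The comparison asks how expression differs between myoblasts kept dividing and the cells after 72 hours in differentiation medium. Median intensities lay between 0.883 and 0.939 on all 6 arrays. Arrays of the proliferating group correlated with each other at 0.913 to 0.949 across probes, those of the differentiated group at 0.906 to 0.938, and arrays from different groups at 0.854 to 0.93. The first principal component held 38.7% of the variance. All 3 differentiated arrays lay on its positive side, between 23.4 and 79.3, and all 3 proliferating arrays on its negative side. Proliferating replicate 1, at -5.6, lay nearer to the differentiated arrays than proliferating replicates 2 and 3, at -76.9 and -59.7.

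Differentiated cultures lost transcripts of dividing cells and gained several muscle transcripts. Top2a, the topoisomerase that untangles chromosomes, fell by 5.36 ± 0.63 (log2 change ± SE, limma adjusted p = 0.0201). Cdc6, which loads the replicative helicase, fell by 4.77. Hmmr and Nuf2, which act at the spindle and kinetochore, changed by -4.57 and -4.47, and the cyclins Ccna2 and Ccnb2 by -4.47 and -4.25. The kinase Nek2, Fam111a, the extracellular protein Reln and the transcript D17H6S56E-5 completed the 10 largest falls. Capn6, a calpain family member, rose by 4.88 ± 0.79 (limma adjusted p = 0.0335), and Tmod4, which caps sarcomeric thin filaments, rose by 4.59. Other large rises were those of Lce1f (4.85), a gene of the cornified epidermal envelope, the serpin Serpinb1a (4.29), the triad protein Sypl2 (4.24), Thrsp (3.85), the transcription factor Klf9 (3.84) and Bcam. Snap91 and the kinase Prkcq were also among the 10 largest rises. For Cdc6, Nek2, Thrsp and Prkcq the lower group had a mean intensity under 0.179, the 25th percentile of positive values, so that background limits the size of the change. With a pseudocount of that size their log2 changes were -3.41, -3.18, 2.38 and 2.00, and all 4 passed.

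**Figure D1:**
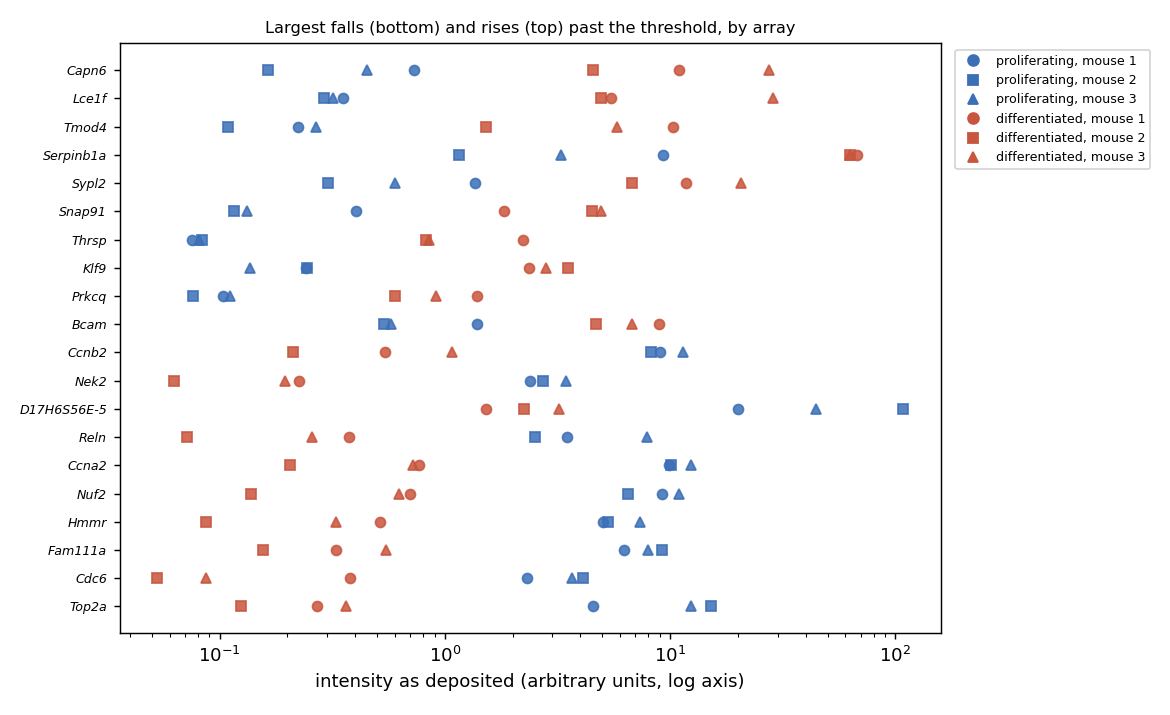
Deposited intensity (arbitrary units, log axis) of the 10 largest rises and 10 largest falls on each of the 6 arrays, with colour for the culture condition and marker shape for the mouse. The groups did not overlap for any of these genes, and Top2a lay between 4.56 and 15.3 in proliferating and between 0.125 and 0.363 in differentiated cultures.

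In all, 132 of 10186 probes passed the threshold, 29 higher and 103 lower in differentiated cells. Of these, 84 had a gene symbol, with 19 rises and 65 falls, and 48 had none here. All 132 changed the same way in 3 of 3 mice with no overlap between the groups, and the smallest change was 2.19 on the log2 scale. Without the threshold the balance was the other way, with 3142 probes higher and 1822 lower in all 3 mice, and 797 higher and 722 lower at an unadjusted p under 0.05 (788 and 1020 after quantile normalization). Of the 10128 probes with 6 values, 20.7% showed no overlap, against 10% by chance. With mouse as a fixed block, 57 probes were higher and 89 lower, and 91 of the 132 calls were kept. With mouse as a random effect, 516 were higher and 538 lower, and all 132 calls were kept. With log2 of the value plus a pseudocount, the split was 127 higher and 266 lower, so that 67.7% rather than 78% of calls were falls. Leaving out proliferating replicate 1 gave 91 higher and 88 lower, and leaving out differentiated replicate 1 gave 8 and 51. Leaving out proliferating replicate 2 or 3, or differentiated replicate 2 or 3, left 0 limma calls, with 986, 1061, 1422 and 1516 probes at an unadjusted p under 0.05.

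Genes of the cell cycle were lower in differentiated cells as groups. Of 22 measured genes of mitosis and chromosome segregation, 13 fell and 19 fell when adjusted over the list alone, with a median change of -3.31, or 9.9-fold lower. Top2a and Hmmr fell most, and limma's camera gave an adjusted p of 1.3e-25 at the preset and adjusted p = 0.211 with an estimated correlation. Of 22 genes of DNA replication, 6 fell over all genes tested and 18 adjusted over the list alone, with a median of -2.28 (camera in limma, adjusted p = 3.79e-19, and adjusted p = 0.211 with an estimated correlation). Cdc6 and Tk1, the thymidine kinase of S phase, fell by 4.77 and 4.23. Of 15 genes of G1 cyclins, cyclin-dependent kinases and E2F, 5 fell and 6 fell adjusted over the list alone, with a median of -1.40 (camera in limma, adjusted p = 1.32e-09, and adjusted p = 0.211 with an estimated correlation). Ccnd1, the D-type cyclin of G1, fell by 3.79 ± 0.58 (limma adjusted p = 0.0308) to a mean intensity of 0.163, in the range limited by background (-2.82 with the pseudocount), and Mybl2, a cell cycle transcription factor, by 3.29. For each of these 3 lists fry gave an adjusted p of 0.0173 (limma). With mouse as a fixed block, limma called 12 of 22 mitosis, 4 of 22 replication and 3 of 15 G1 genes lower. Cdc6 and Tk1 did not pass in that fit (limma adjusted p = 0.0629 and 0.0664), but both passed with mouse as a random effect (0.006 and 0.00658).

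Measured genes of the contractile apparatus were mostly higher in differentiated cells. A shift of each list as a whole rests on camera at the preset correlation. All 16 measured sarcomeric genes were higher in all 3 mice, with a median change of 2.74, or 6.69-fold. Of these 16, 1 rose over all genes tested, Tmod4, and 10 rose adjusted over the list alone. For excitation-contraction coupling and calcium handling, the median of 15 genes was 2.35, with 0 rising over all genes tested and 11 adjusted over the list alone. Pvalb, a cytosolic calcium buffer, had a log2 difference of 2.52 (limma adjusted p = 0.0741). Among embryonic, perinatal and slow isoforms the median of 6 genes was 2.23, with 0 rising over all genes and 5 adjusted over the list alone. Among fast isoforms the median of 7 was 1.98, again with 0 and 5. The slow and cardiac troponin Tnnc1 and the fast troponin Tnni2 had differences of 2.23 and 3.09 (limma adjusted p = 0.128 and 0.0938). Camera in limma gave adjusted p of 1.6e-08 for the sarcomere, 9.83e-07 for excitation-contraction coupling, 5e-04 for the slow and developmental and 0.000293 for the fast isoforms. All 4 lists had an adjusted p = 0.589 with an estimated correlation, and fry gave an adjusted p of 0.176 for each (limma). With mouse as a random effect, limma called 9 of 16 sarcomeric, 9 of 15 coupling, 4 of 6 slow and developmental and 5 of 7 fast genes higher, among them Pvalb, Tnni2 and Tnnc1 (adjusted p = 0.00817, 0.0144 and 0.0258). The fit with mouse as a fixed block called 1 of the 16 sarcomeric genes and 0 genes of the other 3 lists.

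Genes of the dystrophin complex and membrane repair had a median change of 2.04 over 10 genes (camera in limma, adjusted p = 0.000293, and adjusted p = 0.589 with an estimated correlation). Sgcd, a sarcoglycan of that complex, rose by 2.87 ± 0.45, as 1 of 10 over all genes tested and 1 of 5 adjusted over the list alone. Among 22 genes of muscle energy metabolism the median was 2.03 (camera in limma, adjusted p = 7.21e-07, and adjusted p = 0.589 with an estimated correlation). Phkg1, the catalytic subunit of muscle phosphorylase kinase, rose by 2.98 ± 0.51 from a mean intensity of 0.127, in the range limited by background (1.96 with the pseudocount), as 1 gene over all tested and 1 of 11 adjusted over the list alone. All 20 genes of nuclear-encoded oxidative phosphorylation had positive differences, with a median of 0.89 and 0 passing singly on either adjustment (camera in limma, adjusted p = 0.000257). That list had an adjusted p = 0.708 with an estimated correlation, and fry gave an adjusted p of 0.212 for it and 0.176 for the dystrophin and energy lists (limma). The random effect fit in limma called 5 of 10 dystrophin complex and 12 of 22 energy metabolism genes higher. With mouse as a fixed block, limma called 1 of 10 dystrophin complex and 2 of 22 energy metabolism genes higher. Neither Sgcd nor Phkg1 passed in that fit (limma adjusted p = 0.0516 and 0.0625), nor did Serpinb1a and Snap91 (0.0548 and 0.0665). All 4 passed with mouse as a random effect (limma adjusted p = 0.004, 0.00658, 0.00525 and 0.00634).

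**Figure D2:**
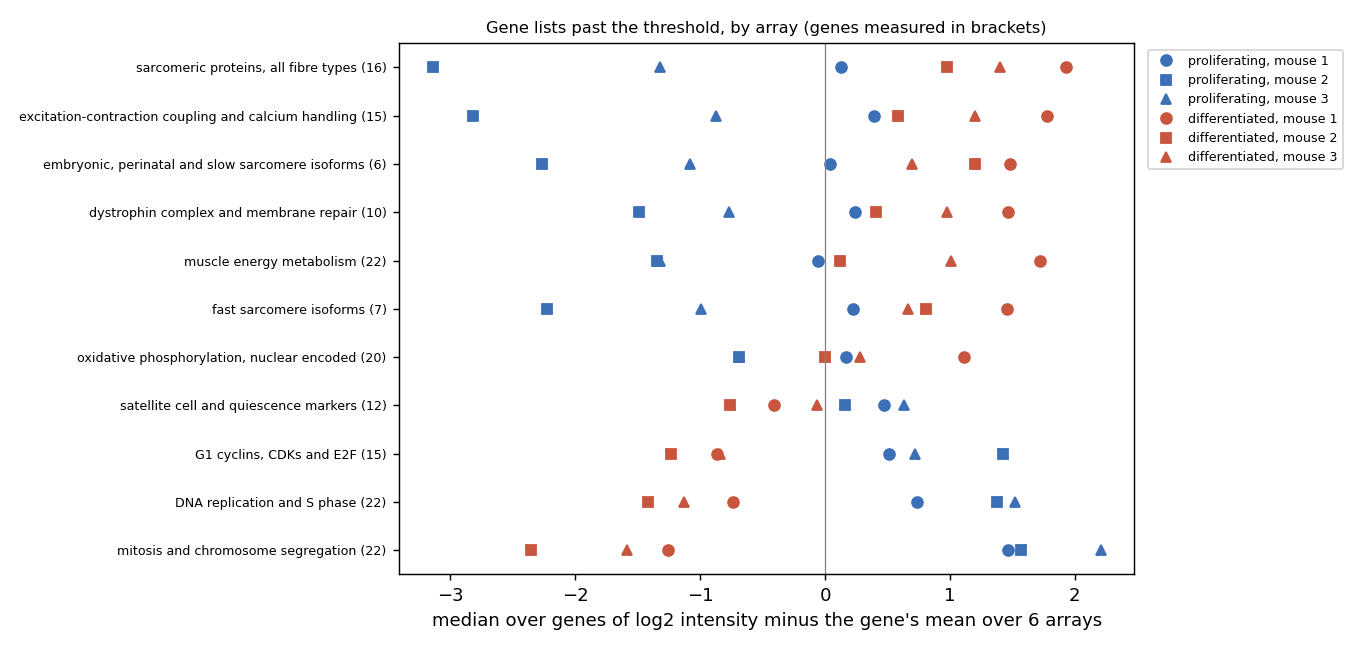
Median over the genes of each list of log2 intensity minus the gene's mean over the 6 arrays, with colour for the culture condition, marker shape for the mouse and the number of genes in brackets. In the mitosis list the proliferating arrays lay between 1.47 and 2.21 and the differentiated arrays between -2.36 and -1.26, and in the sarcomere list proliferating replicate 1 lay at 0.13 while replicates 2 and 3 lay at -3.14 and -1.32.

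Of 14 measured regulators of myogenesis and their partners, 0 passed over all genes tested and 2 rose adjusted over the list alone, Mef2c and Myf6 (limma adjusted p = 0.0218 for each on that adjustment). Mef2c, a transcription factor of muscle differentiation, and Myf6, a late myogenic factor, had log2 differences of 2.95 and 2.74 (limma adjusted p = 0.082 and 0.0978 over all genes tested). With mouse as a block both passed (limma adjusted p = 0.0495 for each). Every gene named by the rule that passed in that fit had this same value, just under the threshold. At an adjusted p under 0.01 limma called 0 probes in it, so passing or missing there can turn on small differences. Myog, the factor that drives terminal differentiation, had intensities of 142, 18.3 and 44.8 in proliferating and 210, 83.7 and 112 in differentiated cultures of mice 1, 2 and 3 (limma adjusted p = 0.467). Myod1 and Myf5, the factors of committed myoblasts, had differences of -0.74 and -0.26 (limma adjusted p = 0.418 and 0.944). Myf5 had intensities of 20.7, 21.4 and 11.7 in proliferating and 74, 13 and 3.15 in differentiated cultures, and its difference was -1.43 without differentiated replicate 1 and 0.84 without differentiated replicate 3. The inhibitors Cdkn1a and Cdkn1c had differences of 1.32 and -1.16, Id3, an antagonist of myogenic factors, -1.83, and the growth inhibitor Mstn 1.16, and none of the 4 passed without mouse in the model. On leaving out 1 array, the difference ranged from 0.44 to 2.22 for Mstn and from -1.82 to -0.30 for Cdkn1c. Muscle creatine kinase, Ckm, had intensities of 7.05, 0.103 and 1.49 against 51.4, 1 and 47.9, and did not pass (limma adjusted p = 0.402). It was higher in 3 of 3 mice, and came nearer the threshold with mouse as a fixed block or a random effect (limma adjusted p = 0.0516 and 0.0672). Tnnt3, a fast troponin, and Chrna1, an acetylcholine receptor subunit, had differences of 2.29 and 0.38 and did not pass. The fit with mouse as a random effect called Id3 lower and Cdkn1a and Tnnt3 higher, each the same way in 3 of 3 mice (limma adjusted p = 0.0115, 0.0426 and 0.0325), while with mouse as a fixed block none of these 3 passed.

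Satellite cell and quiescence markers had a median of -0.72 over 12 genes (camera in limma, adjusted p = 0.0104 at the preset, and adjusted p = 0.589 with an estimated correlation). Of the 12, 4 were lower and 2 higher in all 3 mice, and fry gave an adjusted p of 0.212 (limma). A fall of the whole list thus rests on the preset correlation and stays a hypothesis. Vcam1, an adhesion molecule of satellite cells, fell by 3.13, the 1 of 12 that passed on either adjustment. The FGF and growth factor response list did not pass (camera in limma, adjusted p = 0.661, pointing down with a median of 0.24), but 2 of its 24 genes fell on either adjustment, Fosl1, an AP-1 subunit, by 3.49 and Plaur, the urokinase receptor, by 3.17. Neither passed with mouse as a fixed block (limma adjusted p = 0.0664 and 0.0791), but both passed with mouse as a random effect (0.00752 and 0.0103). Wif1, a secreted Wnt inhibitor, rose by 2.98 from a mean intensity of 0.116, also in that range (1.86 with the pseudocount), as 1 of 24 genes of the Wnt list (2 adjusted over the list alone), whose camera adjusted p in limma was 0.661.

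Lists of extracellular matrix and of ribosome biogenesis had medians of -0.50 and -0.24 and missed the threshold (camera in limma, adjusted p = 0.0511 for both). Both passed with mouse as a block (0.0371 for both, camera in limma, adjusted), with adjusted p = 0.795 and 0.896 with an estimated correlation in the blocked fit. Of 25 matrix genes 0 passed over all genes tested and 2 rose and 6 fell adjusted over the list alone. Nid1, a basement membrane protein, had a difference of -4.14 (limma adjusted p = 0.056, or 0.0114 with mouse as a random effect). Its mean intensity in differentiated cultures was 0.1325, in the range where background limits the size of a change. Lists of 8 other cell types did not pass, with camera adjusted p in limma of 0.326 for adipocyte, 0.647 for both fibroblast and endothelial, 0.661 for macrophage, 0.802 for chondro-osteogenic and 0.98 for smooth muscle, Schwann and erythroid genes. For fibroblast genes the median was 0.42 and the mean -0.11 with the test pointing down, for Schwann and cytosolic ribosomal protein genes the medians were 0.08 and 0.1 with the test pointing down, and for chondro-osteogenic genes the mean was 0.02 with a median of -0.04. Matn2, a matrix protein of the chondro-osteogenic list, had a difference of -2.79 and passed with mouse as a block (limma adjusted p = 0.0495). Fbln1 of the fibroblast list had a difference of -3.20 (limma adjusted p = 0.0649, or 0.0115 with mouse as a random effect). The mixed form of fry, which counts changes in either direction, gave adjusted p of 0.00213 for fibroblast and 0.00299 for chondro-osteogenic genes (limma). It gave 0.304 or more for the lists of the other cell types, so single members of those 2 lists may differ without a shift 1 way.

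The remaining lists did not pass. Camera adjusted p values in limma were 0.138 for cholesterol synthesis, 0.161 for the neuromuscular junction, 0.311 for histones, 0.463 for Notch and 0.495 for myoblast fusion. They were 0.647 for myogenic regulators, for the insulin and IGF pathway and for the proteasome, 0.661 for Id and BMP and for interferon genes, and 0.68 for heat shock. They were 0.98 for cell cycle inhibitors, ribosomal proteins and ER stress. Adjusted over the list alone, 5 heat shock genes rose and 2 fell, 3 Id and BMP genes rose and 2 fell, and 2 interferon genes rose and 1 fell. On that adjustment 1 neuromuscular junction gene also rose and 1 histone gene fell. Hspb7 of the heat shock list had a difference of 4.89 (limma adjusted p = 0.103, or 0.0115 with mouse as a random effect). Mymk, the fusion protein myomaker, had a difference of 2.20 (limma adjusted p = 0.268, or 0.0414 with mouse as a random effect). Fst, which binds activin and myostatin, had a difference of 3.34 with a value missing on 1 array (limma adjusted p = 0.051, or 0.0113 with mouse as a random effect). Among housekeeping genes, Actb had intensities of 105, 286 and 53.9 in proliferating and 25.3, 15.3 and 62.5 in differentiated cultures (limma adjusted p = 0.259). Ppia, Tbp, Hprt and Gapdh had differences of -1.12, -0.24, 0.32 and 0.61, and none passed.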

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

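Testing named features alone and combining the mouse block with quantile normalization were alternatives chosen after seeing the data. All 132 calls, or 84 among named features alone, kept their direction under every alternative. This was largely fixed beforehand: the groups did not overlap for any of the 132, so only rescaling of the arrays could have turned a sign. No list or named gene that passed in either setting reversed. The counts of 29 higher and 103 lower probes became 65 and 178 with a floor at the 10th percentile, 127 and 266 with a pseudocount of 0.179, 136 and 279 without the dimmest probes (6790 tested), and 125 and 263 with a trended, robust prior. Quantile normalization gave 39 and 162. With mouse as a replicate block there were 57 and 89, and with mouse as a random effect 516 and 538 (correlation 0.535). At an adjusted p under 0.01 limma called 0 and 0 probes, against 1519 at an unadjusted p under 0.05. Leaving out 1 array gave 0 to 91 higher and 0 to 88 lower, and leaving out both arrays of mouse 1, 2 or 3 gave 0 limma calls each, with 1424, 854 and 920 at an unadjusted p under 0.05. Fewer arrays leave fewer degrees of freedom, but equally so for each single array left out, so this cannot account for the range among those fits. The cause was not tested for any alternative. Of the lists, 7 shifted up and 4 down; an estimated correlation gave 0 and 0, and fry 0 up and 3 down. Leaving out 1 array gave 7 to 8 lists up and 3 to 6 down. The block ended the call of 8 named genes, 3 other genes and 2 lists passed under it alone, and it changed no other call among them. Among the 132 calls, 21 had the lower group's mean under the 25th percentile of positive values, 0.179, where background limits the size of a change.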

Other observations

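All tests of explanations in this part were chosen after the results they concern were seen, and the genes named first were chosen after their values were seen. Beyond the muscle and cell cycle groups, Hsd11b1, which regenerates active glucocorticoid, rose by 3.07 (limma adjusted p = 0.0305), and Gyg, the glycogenin that primes glycogen, by 3.04 (limma adjusted p = 0.041). The splicing regulator Rbfox1 rose by 2.77 and the imprinted spliceosomal gene Snrpn by 2.37. The neuropeptide gene Gal fell by 3.52, Ugdh, which makes the UDP-glucuronate of glycosaminoglycans, by 3.48, and the connexin Gjc1 by 3.36.

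Genes of fatty acid use were tested as a list written after Cd36, Fabp3, Cpt1b and Ucp3 had been seen to be higher. Without those 4, the median change of 12 genes was 1.04, and 11 of 12 were higher in all 3 mice, among them Crat (1.97), Mlycd (1.37) and Acadl (1.28). Camera with mouse as a block gave p = 0.0011 at the preset and p = 0.22 with an estimated correlation, so a shift of the whole set stays a hypothesis. For circadian clock genes without Dbp, Nr1d2, Bhlhe40 and Rora, the median of 9 genes was 0.70, with 5 of 9 higher in all 3 mice and p = 0.2 with an estimated correlation (blocked camera). Of all 10128 probes with 6 values, 3142 were higher in all 3 mice.

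Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 132 calls, and the highest of the others gave 0. With 10 splits the share cannot be under 0.05. In the other splits any difference between the culture conditions lies within the groups and widens their spread, so their counts do not measure chance. Of the others, 3 also part both cultures of every mouse, with 80 to 169 probes at an unadjusted p under 0.05, and 6 keep some together, with 259 to 1032, against 1519 in the real split.

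Proliferating replicate 1 lay nearer to the differentiated arrays than the other proliferating arrays did. A wrong label or a swap is argued against by its mitosis genes, which lay 2.73 (log2) above the highest differentiated array, where those arrays spanned 1.1. The intensity distribution is argued against as the whole cause, since the excess of 76 muscle genes over the other proliferating arrays was 1.66 as deposited and 1.37 after quantile normalization. A share of already differentiated cells may account for it: 63 muscle genes with a log2 difference over 1 lay 27.6% of the way to the differentiated array of the same mouse (95% bootstrap interval over genes 19.8 to 31.4) and 49 cell cycle genes 34.6% (23.6 to 44.7). The intervals give the scatter among genes in 1 culture, not the uncertainty of a share of cells, so their overlap cannot decide this. A difference between mice stays open too: differentiated replicate 1 also exceeded the other differentiated arrays in these muscle genes, by 0.89 as deposited and 0.37 after quantile normalization.

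Falls outnumbered rises among the calls, although more probes were higher (3142) than lower (1822) in all 3 mice as deposited; at an unadjusted p under 0.05 the balance turned with scaling, from 797 higher and 722 lower to 788 and 1020 after quantile normalization. The deposited scaling is argued against as the whole cause of the excess among calls, because 80.6% were falls after quantile normalization. The excess depended on single arrays, with 49.2% falls (91 higher, 88 lower) without proliferating replicate 1 and 86.4% without differentiated replicate 1. Larger spread between mice among rising genes may contribute but stays open: the median replicate SD was 1.15 for 327 probes with a log2 change over 2 and 0.72 for 309 probes with one under -2, but the fits with mouse gave different shares. Falls made up 51% of calls with mouse as a random effect, 61% with mouse as a fixed block, and 76.4% (25 higher, 81 lower) with that block after quantile normalization.

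Lce1f, a gene of the cornified epidermis, rose from 0.353, 0.29 and 0.317 to 5.45, 4.95 and 28.7. Keratinocytes in the differentiated cultures are a possible source, although preplating was used to purify the myoblasts. Of 40 keratinocyte genes written down for this test, 23 were measured, and besides Lce1f the values of Sprr1a (4.40), Scel (2.46) and Trp63 (2.41) among them had been seen. Without these 4, the median change of 19 genes was 0.54, with 9 higher and 2 lower in all 3 mice. Of all 10128 probes with 6 values, 3142 were higher and 1822 lower in all 3 mice. Of 4 measured keratins, Krt6a (0.54), Krt15 (0.60) and Krt17 (0.69) were higher in all 3 mice while Krt1 differed by 0.18. Krt6a lay between 1.3 and 1.99 in differentiated cultures and the other 3 between 0.0439 and 0.31. The latter values lie near or under 0.179, the 25th percentile of positive values, where background limits the size of a change. The median of the 19 genes lies between the bounds set for and against keratinocytes, so that source stays open. No explanation within the myoblasts themselves was tested.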
